A study of Mus musculus with 4 samples.

How the data were processed

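Total RNA from 4 HT22 cultures was profiled, 1 library for each combination of lentivirus (control negative or aimed at Neat1) and culture (normal or OGD). Per the labels' protocols, RNA was isolated with TRIzol, broken into fragments of about 200 base pairs, copied to double-stranded cDNA with deoxy-UTP in 1 strand and amplified by PCR. No step of poly(A) selection or ribosomal RNA removal is named in the sources used here. Per the submitters' processing notes, reads were aligned with TopHat2 to mm10. The aligner's version, the counting program, the annotation and whether counting used strand are not given in the sources used here, so reads of a gene and an overlapping or antisense neighbour may not be separable.

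The authors deposited 4 tables, each comparing a pair of libraries. Per the file headers they hold size-factor scaled mean counts per gene (a signal per library, under headings used by the DESeq package), a fold ratio, its log2, a p-value and an adjusted p-value. Each table also holds a pair of columns headed by sample number, whose unit is not named. The deposited values of these columns were read as FPKM, from the values. Columns were tied to libraries by the sample numbers in the titles and headers, and the scaled counts to the numbered columns by which genes stood at 0 but for rounding. The number of value columns without a sample was 0.

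Because each scaled count is a whole read count divided by 1 size factor per library, whole reads were recovered from the deposited signal. At a tolerance of 1e-06 of a read, 100% of values came out whole, and both tables that hold a library gave the same reads. A gene missing from a library's tables was counted as 0 reads. The plan made before the data were examined had separate branches for counts and for length-normalised values, and the counts branch was applied to the recovered reads. With 1 library per group no count test was run, and no p-value was computed. A fit of lentivirus and culture without their interaction would leave 1 residual degree of freedom and was not run. The tables held 20089 genes, of which 19950 matched an identifier of GENCODE mouse release 21 (GRCm38), used for names and coordinates, and 139 did not.

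TMM factors were computed with edgeR 4.0.16 in R 4.3.3 over all 4 libraries, and were 1.05, 1.03, 0.893 and 1.03 in the order control normal, knockdown normal, control OGD and knockdown OGD. Ratios and intervals were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. Each comparison used the log2 ratio of CPM with 0.5 CPM added, over genes with at least 20 reads in the higher library, which understates the ratio of low genes. A gene was counted past the size rule at a 2-fold ratio. Intervals of a ratio are exact conditional binomial, those of a level exact Poisson, both at 95%, and folds against 0 reads are bounds computed against 3 reads. Folds and all intervals are computed without the added 0.5 CPM, so an interval need not centre on its log2 ratio. Between 12020 and 13813 genes had at least 20 reads in a library.

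The genes named were fixed by rule: in each comparison the 8 highest and 8 lowest by log2 ratio among genes with at least 100 reads in the higher library, leaving out clone, predicted, microRNA and small-RNA names. Up to 4 members of each gene list with the largest ratio were added, along with the 5 highest and 5 lowest differences between the knockdown ratios, and Neat1 and Malat1. Of the genes this rule takes, 1 is not reported here. The 22 gene lists were also fixed then, and 522 of their 532 symbols matched a gene with reads, older symbols being matched through synonyms. For a list, the median over members past the floor was placed among 10000 random lists of the same size drawn from 20 bins of expression, as a description of these libraries. The size rule was tested on simulated data that varied by Poisson counting alone, scaled by total counts, with 200 changed genes per comparison. Of the genes changed by 1.5 on the log2 scale 96 of 100 were recovered for knockdown in normal culture, 93 for knockdown under OGD, 97 for OGD in control cells and 100 for OGD in knockdown cells. Between 0 and 4 unchanged genes passed per comparison. By its construction this simulation holds no variation between cultures.

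Alternatives planned before the data were examined were total counts and median-of-ratios size factors in place of TMM, 0.1 or 2 CPM added, a floor of 100 reads or none, and the deposited FPKM ratio. Added after the data were seen were the leave-out of 626 genes, the FPKM ratio for Neat1 and the alternatives for named genes. No library could be left out, since each comparison holds 1 per group.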

Results

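Gene expression was measured by RNA sequencing in HT22 cells, an immortalised mouse hippocampal neuronal line. The design crossed a lentivirus aimed at Neat1, a long noncoding RNA that forms the scaffold of nuclear bodies called paraspeckles, with the culture condition. Cells carried either a control negative lentivirus or the Neat1 lentivirus, and were kept in serum-containing medium (normal culture) or deprived of oxygen and glucose (OGD), a cell model of ischaemia. Each of the 4 groups held 1 library, so no difference given here has a replicate check. The libraries held 18596774 reads assigned to genes for control cells in normal culture, 20764430 for knockdown cells in normal culture, 17232866 for control cells under OGD and 19066951 for knockdown cells under OGD. Ratios are log2 ratios of CPM, read counts scaled to library size with TMM factors, with 0.5 CPM added. Intervals are 95% and are computed, as folds are, without the added 0.5 CPM. They cover counting error only, since each group holds 1 library. The reads carried no molecular identifiers, so copies made by PCR were counted as reads. A gene was counted as higher or lower at a 2-fold difference, a rule of size with no test behind it.

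The target itself was lower with the Neat1 lentivirus in each culture, but by less than the 2-fold of the size rule. Among genes with at least 100 reads, log2 ratios had an SD of 1.26 for knockdown in normal culture and 0.594 for knockdown under OGD. Neat1 (ENSMUSG00000092274, chromosome 19, 5824708 to 5845478 on GRCm38, minus strand, annotated as a long intergenic noncoding RNA) stood at 193 CPM in control cells in normal culture (exact Poisson interval 187 to 199) and at 121 CPM in knockdown cells (116 to 125). That is a 1.60-fold lower level (1.52 to 1.68). Under OGD it stood at 74.4 CPM in control cells (70.1 to 78.8) and 42.1 CPM in knockdown cells (39.3 to 45.1), 1.77-fold lower (1.61 to 1.94). OGD went with a larger difference than the lentivirus did: Neat1 was 2.60-fold lower under OGD in control cells (2.43 to 2.78) and 2.87-fold lower in knockdown cells (2.65 to 3.10). With the deposited FPKM values in place of reads, the log2 difference with knockdown under OGD shrank from -0.81 to -0.29. In control cells FPKM fell from 51.0 in normal culture to 12.9 under OGD, a larger fold than by reads. In knockdown cells it fell from 29.7 to 10.5. Reads were counted per gene, so the short and long Neat1 isoforms were not separated. Malat1, the neighbouring nuclear noncoding RNA on chromosome 19, was 1.45-fold higher with knockdown in normal culture (1.35 to 1.57). Under OGD its log2 ratio was -0.13 with TMM scaling and 0.08 with total counts.

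**Figure D1:**
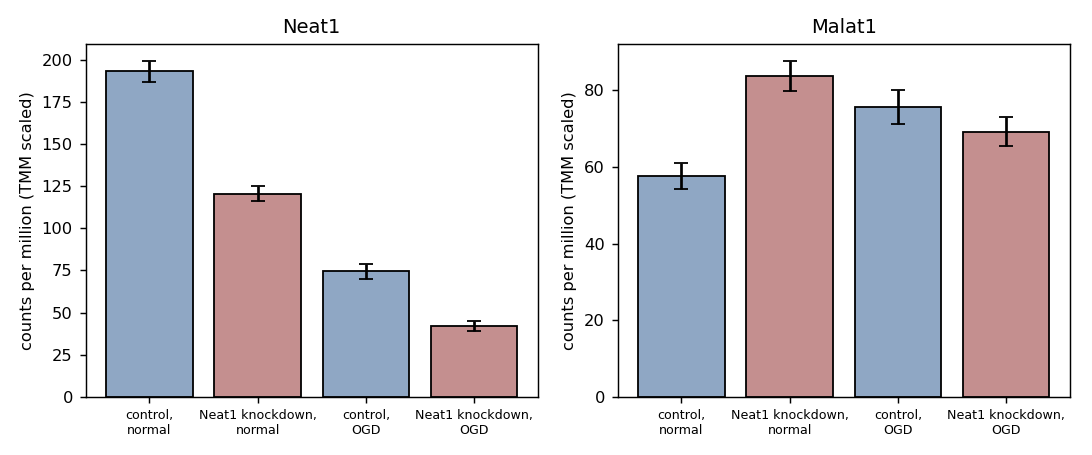
Bars give TMM-scaled CPM of Neat1 (left) and Malat1 (right) in the 4 libraries, 1 per group, and error bars the exact Poisson 95% interval of the read count. Neat1 stands at 193, 121, 74.4 and 42.1 CPM from left to right.

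Which transcripts differ with Neat1 knockdown in unstressed cells was addressed first. In normal culture the library of knockdown cells held far fewer reads of brain-type transcripts than the control library. The lowest were Pcsk1n, a neuroendocrine peptide precursor (10 against 17385 reads, 1905-fold lower, 1035 to 3972), Nrgn, a postsynaptic calmodulin-binding protein (19 against 21469 reads), and the neuropeptide gene Cck (1 against 5133 reads). Cdk5r2, Ddn, Adgrb1, Ckb and Nrxn2, genes with known roles in neurons, followed with log2 ratios between -8.89 and -8.44. Of 20 measured members of the neuronal list, 18 were lower and 0 higher, with a median of -4.45, below every one of 10000 expression-matched random lists. The vesicular glutamate transporter Slc17a7 and the NMDA receptor subunit Grin1 both stood at -8.21. Markers of other cell types moved the same way: 10 of 16 were lower and 1 was higher, among them the oligodendrocyte factor Olig1 (1 against 1622 reads) and the endothelial claudin Cldn5 (1 against 326 reads). Their median was -2.84, and -3.22 with members at 0 reads set to their bound. The control library stood apart from the other 3 libraries as well, with 1443 genes at least 2-fold above each of them and 128 at least 16-fold above.

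Highest with knockdown were Dusp2, a MAP kinase phosphatase (116 against 0 reads, at least 35.3-fold higher), the protease gene Tll1 (117 against 3 reads), and Cd74, the MHC class II invariant chain (9.89-fold, 7.50 to 13.3). Tmem86b, Asb5, Hist1h4h, Skap1 and Zfp566 had log2 ratios between 2.42 and 2.57. Histone genes had a median of 0.93, above every random list, with 9 of 20 members higher and 2 lower; Hist1h3a stood at 1.96 and Hist1h2bc at -1.68. Other RNAs without a poly(A) tail were higher in the same library: ribosomal RNA repeat genes took 4.32% of its reads against 1.81%, and small nuclear RNAs held 685 reads against 383. Integrated stress response genes (ATF4 and CHOP targets) had a median of 0.28, with 18 of 22 above 0 and 1 higher by the size rule, the cystathionine gamma-lyase gene Cth (1.71, 1.42 to 2.55). NRF2 antioxidant genes had a median of 0.29, with Hmox1, the stress-inducible haem oxygenase, at 1.47 and Gstm1, a glutathione transferase, at -1.08. Ribosomal protein genes had a median of 0.21 with 34 of 35 above 0. Endoplasmic reticulum chaperones had a median of -0.25 with 15 of 20 below 0, and 1 was lower by the size rule, the co-chaperone gene Dnajb9 (-1.06). Xbp1 at -0.94 and Hsp90b1 at -0.71 did not pass it. Immediate early genes had a median of -0.20, and the 7 lower members included the activity-regulated Egr3 (0 against 593 reads) and Arc (-3.09). Egr3, Arc and Fosb belonged to the genes that, like the brain-type transcripts, were lower with knockdown in normal culture and higher with it under OGD. Hypoxia genes had a median of -0.24 and glycolytic genes -0.11.

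Medians of the remaining lists in normal culture were 0.04 for heat shock, -0.11 for cholesterol synthesis, 0.11 for p53 targets, 0.10 for apoptosis, 0.21 for interferon response, 0.24 for NF-kB and inflammation (percentile 98.2 of its random lists), -0.04 for extracellular matrix, 0.09 for nuclear OXPHOS (respiratory chain subunits), -0.05 for the mitochondrial genome and -0.04 for paraspeckle proteins. Of the 25 paraspeckle protein genes 0 passed the size rule in either direction, with Rbm7 at 0.93 and Hnrnpr at -0.89 the farthest. Mitosis and DNA replication, at -0.03 and 0.01, took a different sign under another scaling.

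Of 14554 genes with at least 20 reads in the higher library, 910 were higher and 2374 lower with knockdown in normal culture. Without the 626 genes that were both lower with knockdown in normal culture and higher with knockdown under OGD, a leave-out chosen after the data were seen, 910 were higher and 1748 lower, a subtraction that their definition fixes. With 2 CPM added in place of 0.5, 283 were higher and 1587 lower, and with a floor of 100 reads 364 and 1297.

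Under OGD, the second comparison of the lentiviruses, knockdown cells had lower medians of endoplasmic reticulum chaperones and integrated stress response genes, and a higher median of immediate early genes, than control cells. All 20 chaperone-list members were below 0 with TMM scaling (17 of 20 with total counts), 4 of them by at least 2-fold, and their median of -0.73 lay below every random list. With total counts 2 passed the size rule and the median was -0.53. Xbp1, the transcription factor of the unfolded protein response, stood at -1.72 (-1.85 to -1.61), Syvn1, an endoplasmic reticulum ubiquitin ligase, at -1.23, and Creld2 and Herpud1 each at -1.13. Integrated stress response genes had a median of -0.44 with 16 of 22 below 0, but 1 lower and 0 higher by the size rule (0 lower and 1 higher with total counts). Members included the amino acid transporter Slc7a5 at -1.20, Atf5 at -0.96 and Ddit3 (CHOP) at -0.85, while Atf3 stood at 0.86. Immediate early genes had a median of 0.84 with 10 of 25 higher and 0 lower, including Egr2 at 2.49, Arc at 1.95 and Zfp36, an mRNA-decay factor, at 1.70. Without Arc, Egr3 and Fosb, which moved with the brain-type transcripts, the median was 0.68. The inducible heat shock genes Hspa1a and Hspa1b, near-identical copies whose split of reads is uncertain, stood at 1.06 and 0.91. Cxcl10, an interferon-inducible chemokine, was the highest named gene (380 against 14 reads, 21.3-fold, 12.6 to 39.4).

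Brain-type transcripts moved in the direction opposite to normal culture. Of 22 measured neuronal genes 19 were higher and 1 lower, with a median of 2.12. Camk2a stood at 3.17 and Snap25 at 2.86, and the lower member was Tubb3, at -1.31. Of the 22, 9 had at least 20 reads both in control cells under OGD and in knockdown cells in normal culture. A gene below 20 reads in control cells under OGD passed the floor only by reaching it in knockdown cells. Other cell type markers had a median of 1.65 with 9 of 15 higher and 0 lower, among them the myelin gene Mbp (2.81). Hpcal4, Cadm3, Snhg11, Rgs7bp, Slc24a2, Pacsin1 and Sncb, named as highest, had log2 ratios between 3.21 and 3.60. Lowest were RNAs of the RNA-processing machinery and ribosomal RNA repeats: Rpph1, the RNase P RNA (0 against 246 reads, at least 104-fold lower), its related copy Rprl3 (-4.78), Rmrp, the RNase MRP RNA (-4.18), and AY036118 and CT010467.1, annotated over a ribosomal RNA repeat on chromosome 17 (both -4.03). Casp9, the initiator caspase of the mitochondrial pathway, held 1 read against 134, and Lfng held 10 against 203. Lars2 stood at -3.74 and, like the repeat genes, was higher with knockdown in normal culture (1.42, against 1.28 for CT010467.1). The 3 overlapping repeat genes (CT010467.1, Gm42418 and AY036118) took 4.78% of the control library's reads and 0.341% of the knockdown library's.

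Other lists under OGD had medians of 0.012 for hypoxia (-0.00063 with no floor), 0.12 for heat shock, 0.14 for cholesterol synthesis, 0.13 for p53 targets, -0.30 for apoptosis, 0.13 for interferon response, 0.25 for NF-kB and inflammation, 0.12 for extracellular matrix and -0.26 for the mitochondrial genome. Medians of glycolysis (-0.14), NRF2 antioxidant (-0.04), mitosis (-0.14), DNA replication (-0.12), nuclear OXPHOS (-0.16), ribosomal proteins (-0.14), paraspeckle proteins (-0.06) and histones (-0.09) were positive with total counts, a scaling that moved the median of all genes by 0.19.

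Of 13388 genes tested under OGD, 1437 were higher and 566 lower with knockdown. Higher genes made up 71.7% of the genes past the size rule, and 82.3% with total counts. Without the 626 genes described for normal culture, 811 were higher and 566 lower. With 2 CPM added the counts were 535 and 263, and with a floor of 100 reads 456 and 267.

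**Figure D2:**
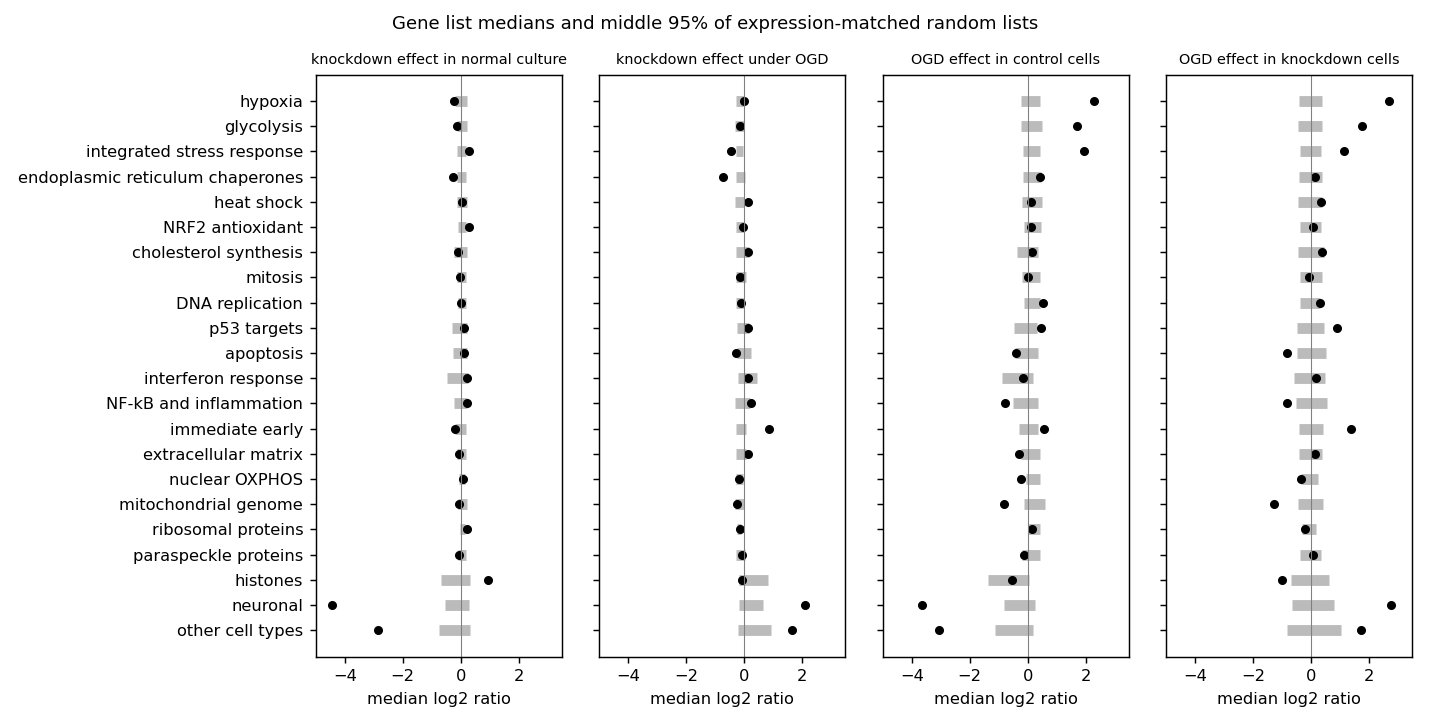
Points give the median log2 ratio of each of the 22 gene lists in the 4 comparisons, and grey bars the middle 95% of medians of 10000 random lists matched on expression. Hypoxia medians stand at 2.30 and 2.71 in the OGD comparisons, and neuronal medians at -4.45 and 2.12 in the knockdown comparisons.

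The response to OGD itself was compared next, within control cells and within knockdown cells. In control cells OGD went with higher hypoxia, glycolysis and stress response genes. Of 22 hypoxia genes 20 were higher, with a median of 2.30, and of 17 glycolytic genes 15, with a median of 1.69. Ndrg1, a hypoxia-induced gene, was 50.6-fold higher (47.4 to 54.2), the endoplasmic reticulum oxidase gene Ero1l 25.5-fold (23.8 to 27.2), and the mitophagy gene Bnip3 16.4-fold (15.5 to 17.4), while the glucose transporter gene Slc2a1 stood at 4.31. Pfkl and Pfkp, subunits of phosphofructokinase, stood at 2.79 and 2.62. Integrated stress response genes had a median of 1.95 with 17 of 22 higher, led by Atf3 (3.19) and the glutathione-degrading enzyme gene Chac1 (3.10). Gdf15, a stress-induced cytokine, was 25.4-fold higher, Dusp4 23.0-fold, Klhl24 26.5-fold and Maff 13.4-fold. Of 22 p53 targets 8 were higher, including the cell cycle inhibitor Cdkn1a (3.64), with a list median of 0.46. Immediate early genes had a median of 0.55, with Fos at 2.69 and Egr3 at -4.38.

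Lower under OGD in control cells were the mitochondrially encoded genes, with a median of -0.82, 6 of 13 lower and 12 of 13 below 0. NF-kB and inflammation genes had a median of -0.79 with 7 of 16 lower and 3 higher. The neutrophil chemokines Cxcl5 (-4.28) and Cxcl1 (-3.44) stood opposite to Ptgs2, the inducible cyclooxygenase, at 2.88. Of the 25 paraspeckle protein genes 4 were lower, Sfpq (-1.73), Rbm14 (-1.69), Pspc1 (-1.62) and Fam98a (-1.33), and Rbm7 was higher (1.18), with a list median of -0.13. Over all genes tested in this comparison 22.2% were lower. The named lowest genes, Pcsk1n, Nrgn, Cdk5r2, Cck, Ddn, Ckb, Fbxl16 and C1qtnf4, had log2 ratios between -9.17 and -7.59. They belonged with the transcripts high in the control library in normal culture, which is the reference here: the neuronal median was -3.63 with 15 of 20 lower, and that of other cell types -3.05 with 10 of 16 lower. Medians of the other lists were 0.43 for endoplasmic reticulum chaperones, 0.54 for DNA replication, -0.40 for apoptosis, -0.17 for interferon response, -0.28 for extracellular matrix (0.019 with no floor), -0.21 for nuclear OXPHOS and -0.53 for histones. Those of heat shock (0.13), NRF2 antioxidant (0.11), cholesterol synthesis (0.17), mitosis (0.03) and ribosomal proteins (0.16) were negative with total counts, which moved the median of all genes by -0.23.

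Of 14101 genes, 1320 were higher and 3125 lower under OGD in control cells. Higher genes made up 29.7% of those past the size rule and 18.5% with total counts, where 866 were higher. Leaving out the 626 genes gave 1315 and 2555, and a floor of 100 reads gave 1923 lower genes.

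In knockdown cells OGD went with higher hypoxia, glycolysis and immediate early genes. Of 22 hypoxia genes 20 were higher, with a median of 2.71, and all 17 glycolytic genes were higher (16 with total counts), with a median of 1.77. Ndrg1 was 33.9-fold higher (32.2 to 35.7) and the hypoxia-induced repressor Bhlhe40 stood at 4.61. Hspa1b was 61.7-fold higher (54.2 to 70.5) and Hspa1a 38.9-fold (32.6 to 46.7), near-identical copies whose division of reads is uncertain. Both were already lower with knockdown in normal culture, at -2.13 and -1.47, which is the reference here. Their log2 ratios for OGD were 5.88 and 5.17 in knockdown cells, against 2.84 and 2.64 in control cells. The median of the 16 heat shock genes in knockdown cells was 0.34, within the middle 95% of random lists, with 6 higher (5 in control cells). Immediate early genes had a median of 1.36 with 14 of 25 higher and 24 above 0, including Nr4a1 (3.72) and Fosb (490 against 4 reads). Without Arc, Egr3 and Fosb the median was 1.04. Integrated stress response genes had a median of 1.14 with 13 of 22 higher. Of the p53 targets, 11 of 22 were higher and 4 lower, with a median of 0.90. Ndrg2 (424 against 2 reads), Klhl24, Sp140 (284 against 0 reads, at least 104-fold higher) and Crebrf were the other named genes on this side.

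Lower under OGD in knockdown cells were mitochondrially encoded genes (median -1.30, 9 of 13 lower), histones (-1.01, 10 of 20 lower), apoptosis genes (-0.84, 7 of 21 lower and 2 higher) and NF-kB and inflammation genes (-0.82, 5 of 15 lower and 1 higher). Other RNAs without a poly(A) tail were lower in the same comparison: ribosomal RNA repeat genes took 0.341% of reads against 4.32%, and small nuclear RNAs held 11 reads against 685. Among apoptosis genes Casp9 held 1 read against 102 and Bad, a BCL2-family member, stood at -1.62. Id3, an inhibitor of DNA binding, was 24.1-fold lower (21.7 to 26.9), and Lfng, Rasl11a, Pcyox1l and Ybey had log2 ratios between -4.94 and -4.12. Teddm1b held 0 reads against 219, at least 66.5-fold lower, and Rpph1 and Rprl3 stood among the lowest here too. Neuronal genes had a median of 2.77 (20 of 22 higher) and other cell type markers 1.73 (11 of 15 higher). Medians were 0.15 for endoplasmic reticulum chaperones, 0.05 for NRF2 antioxidant, 0.38 for cholesterol synthesis, -0.06 for mitosis, 0.30 for DNA replication, 0.17 for interferon response, 0.12 for extracellular matrix, -0.34 for nuclear OXPHOS, -0.21 for ribosomal proteins and 0.07 for paraspeckle proteins, of which 5 of 25 were lower and 0 higher, Sfpq (-1.68), Rbm14 (-1.60) and Fam98a (-2.08) among them.

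Of 14071 genes, 2682 were higher and 2375 lower under OGD in knockdown cells, and 2119 and 2373 without the 626 genes. A floor of 100 reads left 1635 higher, and 2 CPM added left 1542 lower.

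Whether the knockdown went with the same differences in each culture was compared across genes, which are not independent replicates. The 2 knockdown comparisons share no library. Over 12856 genes their log2 ratios had a Pearson correlation of -0.35 and a Spearman correlation of -0.05, and with a floor of 100 reads -0.25 and 0.06. Higher in both cultures were 121 genes, against 47.5 for independent lists, and lower in both 88 against 59.7. Higher in normal culture and lower under OGD were 46, which is 2.19 times the number for independent lists, and lower in normal culture and higher under OGD 626 against 135. Each of the 4 combinations exceeded independence. The 626 genes hold brain-type transcripts such as Pcsk1n (-9.84 in normal culture, 2.66 under OGD), which weigh on the negative Pearson correlation. Neither correlation was computed without these genes. The OGD responses of control and knockdown cells, which also share no library, had a Pearson correlation of 0.16 and a Spearman correlation of 0.44 over 13086 genes, and 0.43 and 0.65 with a floor of 100 reads. Higher under OGD in both were 795 genes against 229 for independent lists, and lower in both 856 against 348. Lower in control cells and higher in knockdown cells were 606 against 412, and the reverse 41 against 194.

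Among genes with at least 100 reads, 32 were higher and 34 lower with knockdown in both cultures, against 6.69 and 15.5 for independent lists. Genes of opposite direction exceeded independence too, with 16 genes higher then lower (3.23 times) and 145 lower then higher (6.91 times). The genes named here were chosen after their values were seen, by the smaller of both ratios. Cd74 stood at 3.10 in normal culture and 2.79 under OGD, Hist1h3a at 1.96 and 1.83, and the muscle intermediate filament gene Des at 1.82 and 2.65. On the lower side were the matrix protein gene Spon2 (-2.21 and -2.15), the water channel gene Aqp1 (-1.99 and -2.19), Medag (-1.69 and -1.96) and the collagen gene Col6a2 (-1.71 and -1.37).

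In the authors' deposited tables, which compare libraries and not conditions, genes were marked as changed at an unadjusted p-value below 0.05. The authors' deposited table marked 60 genes up and 859 down for knockdown in normal culture, and 138 up and 234 down for knockdown under OGD. For OGD the authors' deposited table marked 213 up and 601 down in control cells, and 211 up and 119 down in knockdown cells. Neat1 was marked down in the authors' deposited table for normal culture alone, with an adjusted p-value of 0.693.

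**Figure D3:**
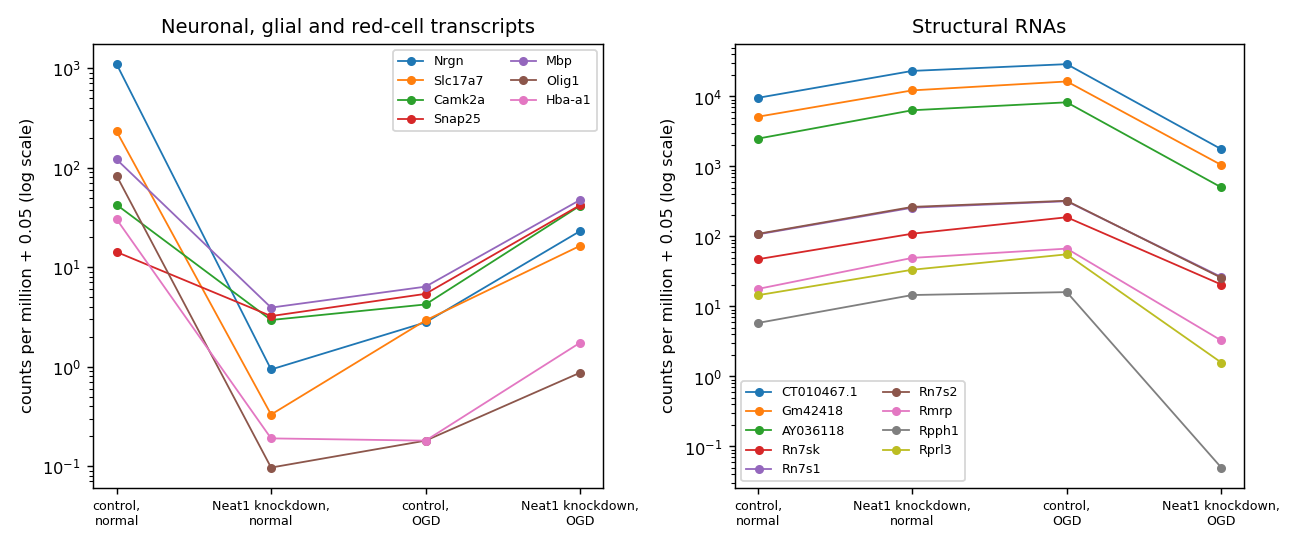
Points give CPM plus 0.05 on a log axis for 7 neuronal, glial and red-cell genes (left) and 9 structural RNA genes (right) in the 4 libraries, with lines joining the values of a gene. Nrgn stands at 1095 CPM in control cells in normal culture and at 22.9 CPM in knockdown cells under OGD, and CT010467.1 stands at 1767 CPM in the latter.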

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

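These results stand out because the knockdown or OGD effect was at least 2-fold in each of the compared conditions and of opposite sign. Each condition holds 1 library, so no difference was tested. All tests in this part were chosen after the result was seen.

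For the knockdown effect, the OGD value minus the normal-culture value was 6.57 on the log2 scale for the neuronal list (-4.45 in normal culture, 2.12 under OGD) and 4.49 for the list of other cell types (-2.84 and 1.65). Among single genes it was 12.5 for Pcsk1n and for Nrgn, 11.4 for Ddn, 11.1 for Fbxl16, 10.9 for Cck and for Ckb, 10.7 for Cdk5r2, 10.5 for Adgrb1, 10.4 for Nrxn2, 10.1 for Sncb, 8.67 for Pacsin1, 8.53 for Rgs7bp, 7.49 for Cadm3, 7.08 for Hpcal4, 7.06 for Slc24a2 and 4.55 for Snhg11. In the other direction it was -6.31 for Rpph1, -5.97 for Rprl3, -5.63 for Rmrp, -5.38 for AY036118, -5.31 for CT010467.1 and -5.16 for Lars2. For the OGD effect, the value in knockdown cells minus that in control cells was 6.40 for the neuronal list, 4.77 for other cell types and 9.52 for C1qtnf4. For Pcsk1n, Nrgn, Ddn, Fbxl16, Ckb, Cck, Cdk5r2, Rpph1 and Rprl3 it equals the value given for the knockdown effect by construction.

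Transcripts of brain tissue were high in the control library in normal culture and in the knockdown library under OGD. The neuronal median of 2.12 under OGD does not decide whether knockdown lowers neuronal genes of the cells in either culture. The list was flagged for opposite signs, so that value is no independent test. Brain RNA in the knockdown library under OGD, if present, could also hide a lower level. Of the 22 neuronal genes measured there, 9 had at least 20 reads in both libraries without the pattern. A knockdown effect that depends on the culture stays open, untested. RNA of brain tissue in the knockdown library under OGD is a candidate source, since the fixed markers of other cell types had a median of 1.65 there (7 of the 15 measured had at least 20 reads in both libraries without the pattern), with Mbp at 47.2 CPM, the neuronal Snap25 at 41.8 and the red-cell globin Hba-a1, outside the fixed lists, at 1.69. Intact brain RNA of the same makeup is argued against for the control library in normal culture: across the 626 genes of the pattern the excess there over that in the other library spanned 6.35 log2 units between the 5th and 95th percentiles, such as 54.2-fold for Nrgn and 0.397-fold for Aldoc. A GC trend of that whole library is argued against too, since the GC-richest and GC-poorest of 10 bins of well-covered genes differed by -0.16, but brain RNA that lost its GC-poor transcripts may fit, since the excess ratio went up with GC content (Spearman rho 0.547 across the pattern's genes).

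Structural RNAs were low in the knockdown library under OGD, with 9 of 9 genes at least 4-fold below the control. Loss of every RNA without a poly(A) tail is argued against by the histone median of -0.087, with 3 of 19 members higher and 3 lower. That median lay low among its random lists, at percentile 4.81. Elsewhere histones moved with the structural RNAs (0.93 for knockdown in normal culture, -1.01 for OGD in knockdown cells) or against them (-0.53 for OGD in control cells). Small nuclear RNAs (11 against 346 reads), small nucleolar RNAs (16 against 109) and scaRNAs (18 against 81) were low too. The structural RNAs had a median of 1.26 with knockdown in normal culture. This does not decide on a knockdown that lowers them in either culture. Rpph1, Rprl3, Rmrp, AY036118 and CT010467.1 were flagged for opposite signs, which fixes their sign there. A different carry-over of structural RNAs between libraries may account for their low level under OGD. Ribosomal RNA, 7SK, 7SL, RNase P and RNase MRP moved in 1 direction in each comparison. Under OGD the smallest difference was -3.16. The 9 genes were chosen after the result was seen and include genes named as lowest under OGD. Their shared direction there is therefore no independent support. Several also overlap or are related copies (CT010467.1, Gm42418 and AY036118, and Rpph1 and Rprl3). A knockdown effect on these RNAs that depends on the culture stays open, untested.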

How the results depend on the processing

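No library could be left out, since each group holds 1. The leave-out of 626 genes, the FPKM ratio for Neat1 and all alternatives for named genes were chosen after the data were seen. Apart from the leave-out, of 72 alternative values that answer a comparison, 51 stayed within 1.5 times the count or within the counting or correlation interval, and among the 21 others no Pearson correlation or Neat1 ratio changed sign. Median-of-ratios size factors and 0.1 CPM added moved none of their 10 each. With total counts, genes higher under OGD in control cells went from 1320 to 866 and Neat1 under OGD from -0.81 to -0.61. Deposited FPKM gave 836 for that count, 326 genes lower with knockdown under OGD, and Neat1 ratios of -0.77 in normal culture and -0.29 under OGD. With 2 CPM added, knockdown in normal culture gave 283 higher, knockdown under OGD 535 higher and 263 lower, OGD in knockdown cells 1542 lower, and the correlations were -0.26 for knockdown and 0.32 for OGD. A floor of 100 reads, which tests fewer genes, gave 364 higher and 1297 lower for knockdown in normal culture, 456 and 267 for knockdown under OGD, 1923 lower for OGD in control cells, 1635 higher for OGD in knockdown cells, and Pearson correlations of -0.25 and 0.43. The Spearman correlation of the knockdown effects went from -0.05 to 0.06 with that floor. No filter, which tests more genes, gave 901 lower for knockdown under OGD. Leaving out the 626 genes gave 811 higher for that comparison, a subtraction that their definition fixes. Except where a changed number of genes accounts for it, the cause was not tested.

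Apart from the leave-out, of 352 alternative list medians 292 moved by less than the spread of random lists, 58 moved by more, and 2, of lists outside the middle 95% of random lists, took the other sign, both with no floor: extracellular matrix for OGD in control cells, 0.019, and hypoxia for knockdown under OGD, -0.00063. The cause was not tested. Of 395 alternative values of named genes 249 stayed within their counting interval, or between it and the reported value, and 146 did not. Depth limits folds against few reads: the 10 reads of Pcsk1n in knockdown cells in normal culture leave an interval of 1035-fold to 3972-fold.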

Other observations

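The tests of dilution and of a weaker deprivation in this part were chosen after the result was seen, and the test of GC content and length before.

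Genes that differed with OGD in control and in knockdown cells alike, chosen after their values were seen, lay outside the hypoxia list too. Log2 ratios in control and knockdown cells were 4.44 and 4.37 for the MAP kinase phosphatase gene Dusp4 and 3.68 and 4.66 for Crebrf. On the lower side they were -3.82 and -4.56 for Id3, -3.81 and -3.88 for Them6, -2.84 and -2.71 for Acaca, an acetyl-CoA carboxylase of fatty acid synthesis, and -2.65 and -2.61 for Smad6, an inhibitor of BMP signalling. With at least 100 reads, 673 genes were higher and 598 lower under OGD in both, against 146 and 167 for independent lists.

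Endoplasmic reticulum chaperones had medians below 0 with knockdown in both cultures, -0.25 in normal culture, where 1 of 20 members was at least 2-fold lower, and -0.73 under OGD, where 4 were. Under OGD 20 of 20 members were below 0 with TMM scaling. With total counts 17 were, 2 were at least 2-fold lower and the median was -0.53. GC content and length of the transcripts are argued against as the cause, since the list's median lay at percentile 0 among random lists matched on both, whose lowest median was -0.45. Dilution by brain RNA would lower the transcripts of dividing cells at least as much. It is argued against by the mitosis median of -0.14, or 0.05 with total counts (SD 0.533 over 23 members). The hypoxia median of 0.012 showed no lower hypoxia response as a whole, with 11 of 22 members above 0 and 11 below. Members ran from -2.06 for Pfkfb4 to 0.95 for Kdm3a. Integrated stress response genes had a median of -0.44, so the hypoxia median does not decide on a weaker deprivation. A lower unfolded protein response in Neat1 knockdown cells under OGD is a hypothesis that these tests leave open. They also leave open a weaker deprivation, as a whole or of glucose alone, and variation between cultures, which 1 library per group cannot show.

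Genes with at least 100 reads in one library and 0 in the other were uneven in the comparisons that hold the control library in normal culture. In normal culture 215 had such reads in the control library and 0 in the knockdown library, and 2 the reverse. For OGD in control cells 111 had such reads in normal culture and 0 under OGD, and 0 the reverse. Under OGD 1 gene had such reads in the control library alone and 0 in the knockdown library alone. For OGD in knockdown cells 13 had such reads in normal culture alone and 14 under OGD alone. Xist, the X-inactivation RNA, held 72 and 211 reads in the control library in normal culture and the knockdown library under OGD, against 12 and 16 in the others.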
